A study of Danio rerio with 6 samples.

How the data were processed

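The deposited tables hold raw counts, one whole number per Ensembl gene and library, for 3 CtrlK and 3 DNK libraries. Per the labels, RNA of sorted cardiac endothelial cells was reverse-transcribed and amplified by the MALBAC method, and the libraries were sequenced on an Illumina HiSeq2500. Per the submitters' processing notes, the tools were Trim Galore 0.6.0, HISAT2 2.1.0, HTSeq 0.6.1 and DESeq2 1.22.2 and the genome build was GRCz11. The notes as used here give no role or order for these tools. The strand setting, the minimum alignment quality and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart with certainty. Amplification without molecular identifiers means that counts are not independent molecules, and intervals and floors cover counting error only.

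Groups were taken from the sample titles. The labels differ among themselves about CtrlK. The design text calls these fish wild-type siblings and a label calls them untreated, while the treatment protocol describes the transgene without the Cre driver and the same 4-hydroxytamoxifen treatment as DNK. The protocols also use other group abbreviations for the sorted hearts. The titles were followed throughout.

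Each table has 32520 gene rows and 5 rows that name no gene. These 5 rows held 98.8% ± 0.108 of each CtrlK library's total and 98.5% ± 0.00638 of each DNK library's (SD, n = 3 each), of which the largest was reads under the quality minimum (58.2% ± 0.0493 and 58.7% ± 0.648). They were left out of library sizes and tests. Only 1.15% ± 0.108 of the total in CtrlK and 1.48% ± 0.00638 in DNK was assigned to genes, which gave 174371 to 227373 gene counts per library. The counting may have used settings that do not suit these libraries, which the sources used here do not settle, so what part of the transcripts the counts stand for is open. Names came from a table of gene IDs, which named 29201 of the 32520 IDs. In it 6136 IDs share their name with another ID, often 2 zebrafish copies under 1 human-style name, so an ID is given where 2 tested IDs share a name printed here. Other names can also stand for a copy that was not tested. No genome was used, so no coordinates are given.

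Genes were kept by filterByExpr on the groups (3792 genes) and tested with edgeR 4.0.16 (TMM factors, glmQLFit with robust = TRUE, glmQLFTest, R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Each SE is the absolute log2 fold change divided by the square root of the F statistic. Normalized CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The biological coefficient of variation was 0.330. On simulated counts with these library sizes and means, in which 200 genes were changed, the same steps tested 3426 genes. They recovered 9.68% of 93 tested genes changed 2-fold and 74.2% of 93 changed 4-fold, and called 5 unchanged genes among 83 calls. Changes near 2-fold were therefore mostly below detection at this depth.

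The groups, the tests, the alternatives, 27 gene lists and the rule for named genes were set before the data were examined. The named genes are SMARCA4, kdrl, both NOTCH1 copies, notch2, NOTCH3, dll4 and kdm7aa whatever their values. Added to these are, per direction, the 8 largest changes among called genes whose groups do not overlap, with at least 10 CPM in the higher group and an assigned symbol. From each list, up to 4 called members with the smallest p are named, or, if none was called, 2 members with the smallest p as values. Not every gene the rule takes is printed, and some results are not reported here. List symbols were matched to the name table by symbol, by the human-style name without the copy letter, or by an alias chosen from names alone after the tables were at hand. The pattern for cytosolic ribosomal protein genes also took in the kinases RPS6KA1, RPS6KA3 and rps6kb1a. Lists were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1), adjusted over the 22 lists with at least 5 tested members. By fry 5 lists passed for a shift in 1 direction, namely stress, glycolytic, macrophage and neutrophil, cyclin-dependent kinase inhibitor and endocardial genes, and 18 for change in either direction. With an estimated correlation 0 of the 22 lists passed camera (adjusted p = 0.446 for the first 4 of these 5 and 0.559 for endocardial genes). Shares of marker lists in the gene counts were compared by a two-sided exact permutation test. The 6 libraries were compared in pairs by a chi-square test of counts, whose statistic per degree of freedom was 3.08 to 9.18, and no pair agreed within sampling noise.

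The alternatives were RLE and upper-quartile factors, library size only, no filter, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, robust = FALSE, the replicate number as a block, leaving out each library, a 2-fold minimum, and removal of mitochondrial, ribosomal protein and erythroid genes. After the data were seen, 3 more were added. These were factors from the median ratio over the 200 most abundant genes, factors from the reads counted outside genes, and the log2 ratio of reads outside genes to gene counts as a covariate. Planned corrections for GC content need a genome and were not run.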

Results

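RNA-seq libraries were prepared from cardiac endothelial cells of adult zebrafish (strain Tu) at 7 days after part of the ventricle had been resected. The cells carried a kdrl:eGFP reporter, which marks vascular and endocardial endothelium, and were sorted by their green fluorescence from ventricles of about 15 hearts. In the DNK group, CreER driven by kdrl was activated with 4-hydroxytamoxifen for 3 days before resection, so that endothelial cells expressed a dominant-negative Xenopus Brg1, an altered form of the ATPase of the SWI/SNF chromatin remodelling complex. Per the treatment protocol, the CtrlK group carried the silent transgene and the reporter without the Cre driver, while other labels call these fish wild-type siblings or untreated. An effect of the Cre driver therefore cannot be told apart from that of the dominant-negative Brg1. The same holds for 4-hydroxytamoxifen if the CtrlK fish were untreated. Each group had 3 libraries. The labels do not say what a replicate number marks or whether replicates came from separate pools of fish, so p-values measure only the spread between these libraries, which may be technical. Counts assigned to genes came to 174371, 207325 and 216713 in CtrlK replicates 1, 2 and 3, and to 227373, 223316 and 200646 in DNK replicates 1, 2 and 3. At this depth 3 counts correspond to 13.2 to 17.2 CPM, and 3792 genes had enough counts to be tested.

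The comparison of DNK with CtrlK addresses, per the series title, how endothelial Brg1 acts on Notch signalling during heart regeneration. The transgene is a Xenopus sequence and was not counted, so the labels could not be checked from it. The zebrafish Brg1 gene, SMARCA4 (ENSDARG00000077226), had 54.2 ± 19.9 normalized CPM in CtrlK and 54.8 ± 19.7 in DNK (SD, n = 3 each), a log2 fold change of 0.01 ± 0.54 (SE, adjusted p = 0.994). The other ID with that name had 18 counts in CtrlK and 4 in DNK and was not tested. kdrl, the source of the promoter behind both the sort and the Cre, had 49.8 ± 11.5 CPM in CtrlK and 75.6 ± 11.4 in DNK (SD, n = 3 each), which did not pass (log2 fold change 0.60 ± 0.47, adjusted p = 0.452). kdm7aa, a histone demethylase of the KDM7 family, was 8.14-fold higher in DNK, with 12.7 ± 11.4 CPM against 113 ± 38.0 (SD, n = 3 each, log2 fold change 3.02 ± 0.66, adjusted p = 0.0162). Without CtrlK replicate 2 the log2 fold change was 3.62. The call was lost without DNK replicate 1 (adjusted p = 0.0974) and with limma-voom (adjusted p = 0.0746), over a range of 0.000923 to 0.0974. The ranges given here and below leave out a fit with the ratio of reads outside genes to gene counts as a covariate, in which kdm7aa had an adjusted p of 0.960 and edgeR called 0 genes (219 at an unadjusted p under 0.05).

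Transcripts of 2 Notch receptor genes were higher in DNK. NOTCH1 (ENSDARG00000052094) rose from 66.4 ± 51.4 to 319 ± 105 CPM (SD, n = 3 each), 4.68-fold, with a log2 fold change of 2.23 ± 0.49 (adjusted p = 0.0162), which was 3.07 for NOTCH1 ENSDARG00000052094 without CtrlK replicate 3. notch2 rose from 32.3 ± 16.0 to 110 ± 12.6 CPM (SD, n = 3 each, log2 fold change 1.75 ± 0.49, adjusted p = 0.0453). The second NOTCH1 copy (ENSDARG00000103554) had a log2 fold change of 0.61 ± 0.39 (adjusted p = 0.359), NOTCH3 one of −0.10 ± 0.55 (adjusted p = 0.925), and the ligand gene dll4 one of −0.25 ± 0.36 (adjusted p = 0.709). The differences between the receptors were not tested. Of 13 tested genes for Notch receptors, ligands and processing, 2 rose and 11 did not pass, and the count was also 2 adjusted over the list alone, but 1 by DESeq2 and 1 by limma-voom. The list as a whole did not pass (camera adjusted p = 0.238, adjusted p = 0.559 with an estimated correlation), except with no filter (adjusted p = 0.0190). Among Notch target genes, 5 of 25 listed IDs could be tested and all 5 had positive log2 fold changes, with a median of 0.99. A positive median was common, in 19 of the 22 lists with at least 5 tested members. The untested target IDs had few counts or none and went both ways, as heyl (12 counts in CtrlK and 3 in DNK) and HEY2 (7 and 11) show. NRARP (ENSDARG00000091419), a feedback regulator of the pathway, rose from 1029 ± 320 to 2625 ± 194 CPM (SD, n = 3 each, log2 fold change 1.35 ± 0.27, adjusted p = 0.0119). The other tested members did not pass over all genes, and EFNB2 had a log2 fold change of 1.33 ± 0.46 (adjusted p = 0.0884). Adjusted over the list alone, 3 members passed. The target list passed camera (adjusted p = 0.0386) but not with an estimated correlation (adjusted p = 0.446), nor by fry (adjusted p = 0.0959), nor without CtrlK replicate 2 (adjusted p = 0.165), without DNK replicate 3 (adjusted p = 0.0875) or with libraries scaled to reads outside genes (adjusted p = 0.0576), over a range of 0.0154 to 0.446. The NOTCH1 call was lost without CtrlK replicate 1 (adjusted p = 0.0504), CtrlK replicate 2 (0.0589) or DNK replicate 3 (0.0642), over a range of 0.000125 to 0.0642. The notch2 call was lost without each library except CtrlK replicate 3 (adjusted p = 0.112 and 0.148 without CtrlK replicates 1 and 2, 0.140, 0.114 and 0.0851 without DNK replicates 1, 2 and 3), and also with DESeq2 (0.0947), limma-voom (0.125), no filter (0.0836) or the replicate number as a block (0.0595), over a range of 0.0127 to 0.148. The NRARP call was lost without CtrlK replicate 2 (adjusted p = 0.0583) or DNK replicate 1 (0.0509), over a range of 5.33e-05 to 0.0583. With the covariate the adjusted p was 0.958 for NOTCH1 ENSDARG00000052094, 0.964 for notch2 and 0.960 for NRARP.

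**Figure D1:**
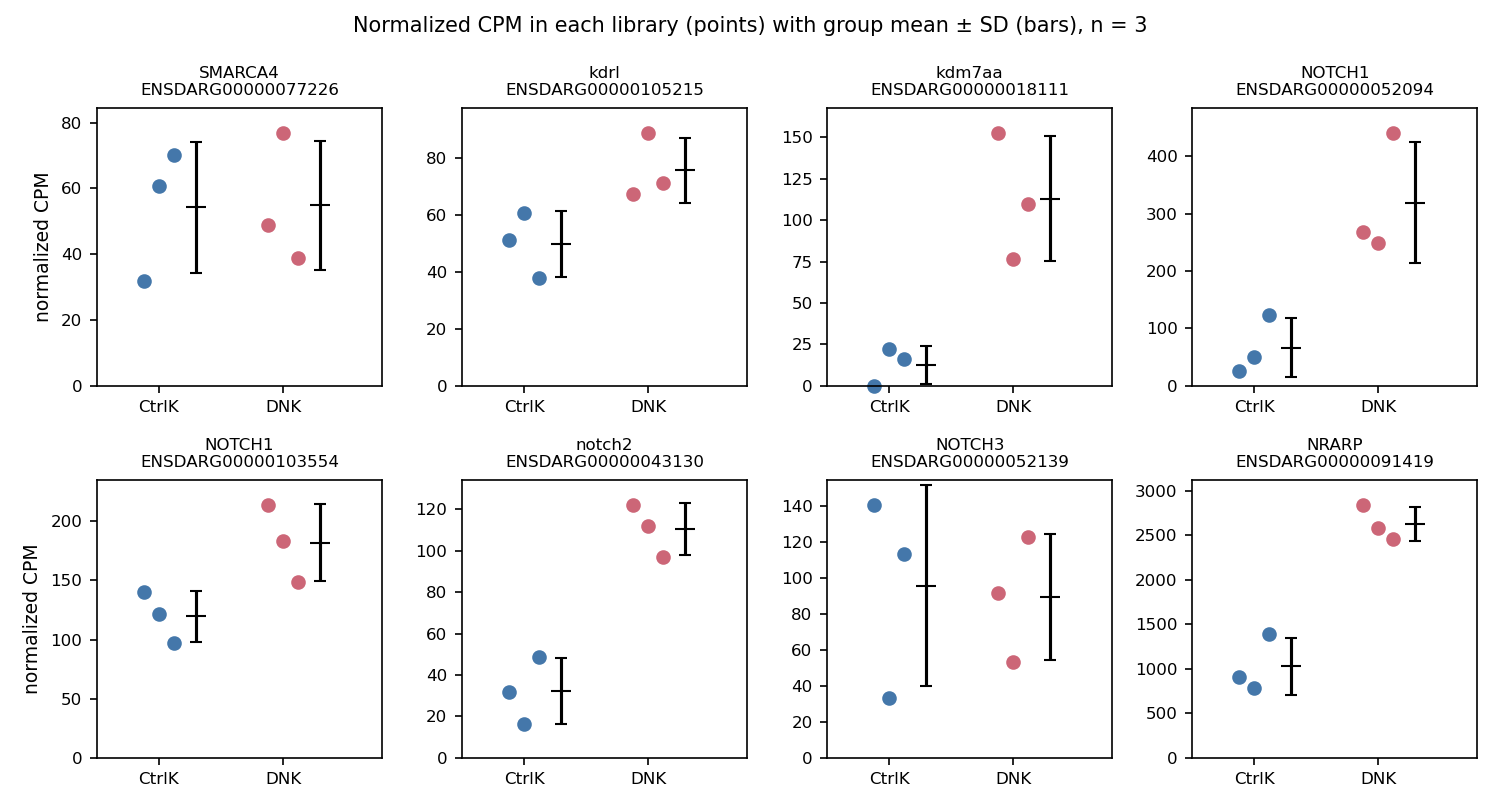
Normalized CPM (linear axes from 0) of 8 genes in each of the 3 CtrlK and 3 DNK libraries, as points, with the group mean ± SD as bars. The 3 DNK libraries lie above the 3 CtrlK libraries for kdm7aa, both NOTCH1 copies, notch2, NRARP and kdrl, of which the second NOTCH1 copy and kdrl did not pass the test, and the groups overlap for SMARCA4 and NOTCH3.

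The largest rises in DNK were in genes that were scarce in CtrlK. ZC3H12A, which encodes an RNase that degrades inflammatory mRNAs, rose 18.1-fold, from 33.5 ± 27.1 to 628 ± 34.4 CPM (SD, n = 3 each, log2 fold change 4.18 ± 0.46 or, without CtrlK replicate 3, 5.11, adjusted p = 0.000589). RASA1 (ENSDARG00000073665), a negative regulator of Ras, had 2 counts in the CtrlK libraries together and 64 in DNK, a ratio of 34.3 (95% counting interval 9.13 to 290, adjusted p = 0.00446), while its other copy (ENSDARG00000035535) had a log2 fold change of −0.54 (adjusted p = 0.410). lgals9l3 had 2 and 62 counts, a ratio of 33.3 (95% counting interval 8.83 to 281, adjusted p = 0.00488). The other rises that met the naming rule were ppp4r1l (log2 fold change 4.01 ± 0.72), NETO2 (3.27 ± 0.53), ZNRF2 (3.06 ± 0.64) and RCBTB1 (3.05 ± 0.61), beside kdm7aa. Without CtrlK replicate 2 the values were 4.77 for ppp4r1l and 4.16 for ZNRF2. The call of RCBTB1 was lost without DNK replicate 2 (adjusted p = 0.0702) and that of ZNRF2 without DNK replicate 1 (0.0839). With limma-voom the calls of ppp4r1l (adjusted p = 0.161), ZNRF2 (0.0995) and RCBTB1 (0.0724) were lost. Large falls that met the naming rule were in zdhhc3a (−3.60 ± 0.81), TMEM178B (−3.23 ± 0.75), or93a8 (−3.11 ± 0.65), prlrb (−2.93 ± 0.83), GAS7 (−2.90 ± 0.56), ABCA12 (−2.57 ± 0.53) and UBE2G2 (−2.55 ± 0.53). or93a8 carries the name of an odorant receptor and had 147 ± 103 CPM in CtrlK and 16.5 ± 4.11 in DNK (SD, n = 3 each). GAS7 fell from 111 ± 8.77 to 14.1 ± 8.73 CPM (SD, n = 3 each, adjusted p = 0.00988), and its call was lost without DNK replicate 1 (adjusted p = 0.0516). The calls of the other named falls were each lost without 1 or more of the libraries. For prlrb this was so for each of the 6 libraries, with adjusted p of 0.0983 to 0.191. With limma-voom the calls of these 6 falls were also lost, with adjusted p of 0.0525 (zdhhc3a) to 0.130 (or93a8), and that of prlrb also with the replicate block (0.0554) and scaled to reads outside genes (0.0553). DNK replicate 1 ended the calls of or93a8 (0.0509), TMEM178B (0.0659), ABCA12 (0.0659) and UBE2G2 (0.0602). DNK replicate 3 ended those of ABCA12 (0.0584), zdhhc3a (0.0520) and TMEM178B (0.0738), DNK replicate 2 that of zdhhc3a (0.0666), CtrlK replicate 3 those of or93a8 (0.0761), UBE2G2 (0.0514) and zdhhc3a (0.140), and CtrlK replicates 1 and 2 that of TMEM178B (0.0674 and 0.0528). The log2 fold changes that moved by over 1.5-fold were −2.38 (or93a8) and −2.80 (zdhhc3a) without CtrlK replicate 3, −4.79 (zdhhc3a), −2.62 (TMEM178B) and −2.34 (prlrb) without DNK replicate 1, and −4.63 (TMEM178B) without DNK replicate 2.

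Some stress, glycolytic and mitochondrially encoded genes rose in DNK, 5 of 21, 2 of 10 and 5 of 10 tested members. Their lists passed camera, but none of the 3 did with an estimated correlation (adjusted p = 0.446 each), and by fry the mitochondrial list did not (adjusted p = 0.0556). Among immediate-early and dissociation stress genes, 5 of 21 tested members rose, 10 adjusted over the list alone, and 18 had positive log2 fold changes (median 1.00, camera adjusted p = 4.33e-05, adjusted p = 0.446 with an estimated correlation). The inducible Hsp70 chaperone gene hsp70.3 rose from 2396 ± 675 to 8710 ± 2444 CPM (SD, n = 3 each, log2 fold change 1.86 ± 0.28, adjusted p = 0.00446), and hsp70l and hsp70.1 rose by 1.56 ± 0.29 and 1.54 ± 0.30. These are close copies, between which reads can be split or dropped. JUND, of the AP-1 family, rose by 1.04 ± 0.26 (adjusted p = 0.0269). All 10 tested mitochondrially encoded genes had positive values (median 1.39, camera adjusted p = 4.33e-05, adjusted p = 0.446 with an estimated correlation), and 5 rose, 7 adjusted over the list alone. MT-CO3, a subunit of cytochrome c oxidase, rose from 2197 ± 550 to 6351 ± 588 CPM (SD, n = 3 each, log2 fold change 1.53 ± 0.25), and MT-CO1 by 1.56 ± 0.30. MT-ND5 and MT-CYB rose by 1.48 ± 0.34 and 1.56 ± 0.39. The MT-ND5 call was lost without DNK replicate 1 (adjusted p = 0.0521) or 2 (0.0702), and the MT-CYB call without CtrlK replicate 1 (0.0826) or 2 (0.0867) or DNK replicate 1 (0.0631) or 2 (0.0939). Both were lost when scaled to the 200 most abundant genes (0.0523 and 0.0689). Of 10 tested genes of glycolysis and glucose uptake, 2 rose, over all genes and adjusted over the list alone, and all 10 were positive (median 0.76, camera adjusted p = 0.00335, adjusted p = 0.446 with an estimated correlation). ALDOA, a fructose-bisphosphate aldolase, rose from 7317 ± 1539 to 27568 ± 2480 CPM (SD, n = 3 each, log2 fold change 1.91 ± 0.23, adjusted p = 0.000799), and PKM, a pyruvate kinase, rose by 1.30 ± 0.34 (adjusted p = 0.0324). The medians of the 3 lists stayed positive under each scaling tried, and were smallest when scaled to the 200 most abundant genes, at 0.86 for mitochondrial, 0.45 for stress and 0.18 for glycolytic genes. Leaving out DNK replicate 1 ended the calls of hsp70.1 (adjusted p = 0.0519), JUND (0.138) and PKM (0.0629). The JUND call was also lost without CtrlK replicate 1 (0.0552), CtrlK replicate 2 (0.0899) or DNK replicate 2 (0.0821), and the PKM call without CtrlK replicate 1 (0.0774), CtrlK replicate 2 (0.0907), DNK replicate 2 (0.0855) or DNK replicate 3 (0.101). The JUND and PKM calls were also lost when scaled to the 200 most abundant genes (adjusted p = 0.115 for JUND and 0.163 for PKM) or with library size alone (0.0580 and 0.0776), and JUND with the replicate block (0.0574).

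Markers of endothelium and of other cardiac cells were compared next. Of 10 tested endothelial markers 1 passed. This was vwf, the von Willebrand factor gene, which rose from 226 ± 99.0 to 684 ± 127 CPM (SD, n = 3 each, log2 fold change 1.59 ± 0.36, adjusted p = 0.0179), also adjusted over the list alone. The endothelial list did not pass (camera adjusted p = 0.138) but did so without CtrlK replicate 2 (adjusted p = 0.0328), without DNK replicate 1 (0.0374) and with no filter (0.00576). With an estimated correlation its adjusted p was 0.446, the upper end of its range. For macrophage and neutrophil markers all 8 tested members were positive (median 0.96, camera adjusted p = 0.00365, adjusted p = 0.446 with an estimated correlation). By edgeR 0 of them passed over all genes, with 4 adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. SPI1, a myeloid transcription factor, had a log2 fold change of 1.74 ± 0.52 (adjusted p = 0.0541), and cd74a one of 0.97 ± 0.31 (adjusted p = 0.0681). Among 9 cardiomyocyte markers, atp2a2a, a calcium pump, rose by 2.03 ± 0.58 (adjusted p = 0.0453) and 8 did not pass, with 2 passing adjusted over the list alone (camera adjusted p = 0.216, adjusted p = 0.446 with an estimated correlation, and 0.000982 by camera with no filter). Among 9 fibroblast and mural cell markers, PDGFRB rose by 1.70 ± 0.40 (adjusted p = 0.0205), also adjusted over the list alone (camera adjusted p = 0.460). The single tested lymphocyte marker, cd8a, fell by 1.38 on the log2 scale (SE 0.33, adjusted p = 0.0226). The share of gene counts held by macrophage and neutrophil markers was 0.122% ± 0.0370 in CtrlK and 0.193% ± 0.00735 in DNK (SD, n = 3 each, exact permutation p = 0.1). That of endothelial markers was 0.198% ± 0.0369 and 0.253% ± 0.0179 (exact permutation p = 0.1), and that of cardiomyocyte markers 0.162% ± 0.0317 and 0.174% ± 0.0217 (exact permutation p = 0.7). Shares that were lower in each DNK library than in each CtrlK library were those of lymphocyte (0.0495% ± 0.00983 and 0.0198% ± 0.000886), thrombocyte (0.103% ± 0.0101 and 0.0730% ± 0.00934) and lymphatic and venous markers (0.0515% ± 0.00430 and 0.0429% ± 0.00171, exact permutation p = 0.1 each). The lymphocyte share was mostly cd8a, so it is not separate from the fall of that gene. The largest part of the thrombocyte share was THBS1, which did not pass (log2 fold change −0.46 ± 0.33, adjusted p = 0.412). Genes not expected in heart endothelium, described below, also held less of the gene counts in DNK. Their summed CPM was 3368 ± 626 in CtrlK and 2099 ± 273 in DNK (SD, n = 3 each). A smaller read background could therefore lower such shares too, and these falls do not show fewer such cells. The exact two-sided test cannot go below 0.1 with 3 libraries against 3. The calls of vwf (adjusted p = 0.0534, 0.0605 and 0.0620) and PDGFRB (0.0534, 0.0630 and 0.0915) were lost without CtrlK replicate 1, without CtrlK replicate 2 and, for vwf, without DNK replicate 1 or, for PDGFRB, without DNK replicate 3. That of atp2a2a was lost without any one of the 6 libraries (0.0771 to 0.178), and that of cd8a without CtrlK replicate 1 (0.0689) or DNK replicates 1, 2 or 3 (0.0737, 0.102 and 0.0786). Scaled to the 200 most abundant genes, vwf (adjusted p = 0.0529), PDGFRB (0.0782) and atp2a2a (0.110) no longer passed, and scaled to reads outside genes cd8a did not (0.0754), nor with no filter (0.0777). The atp2a2a call was also lost with library size alone (0.0758), no filter (0.0616), DESeq2 (0.0866), limma-voom (0.171) or the replicate block (0.0721).

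**Figure D2:**
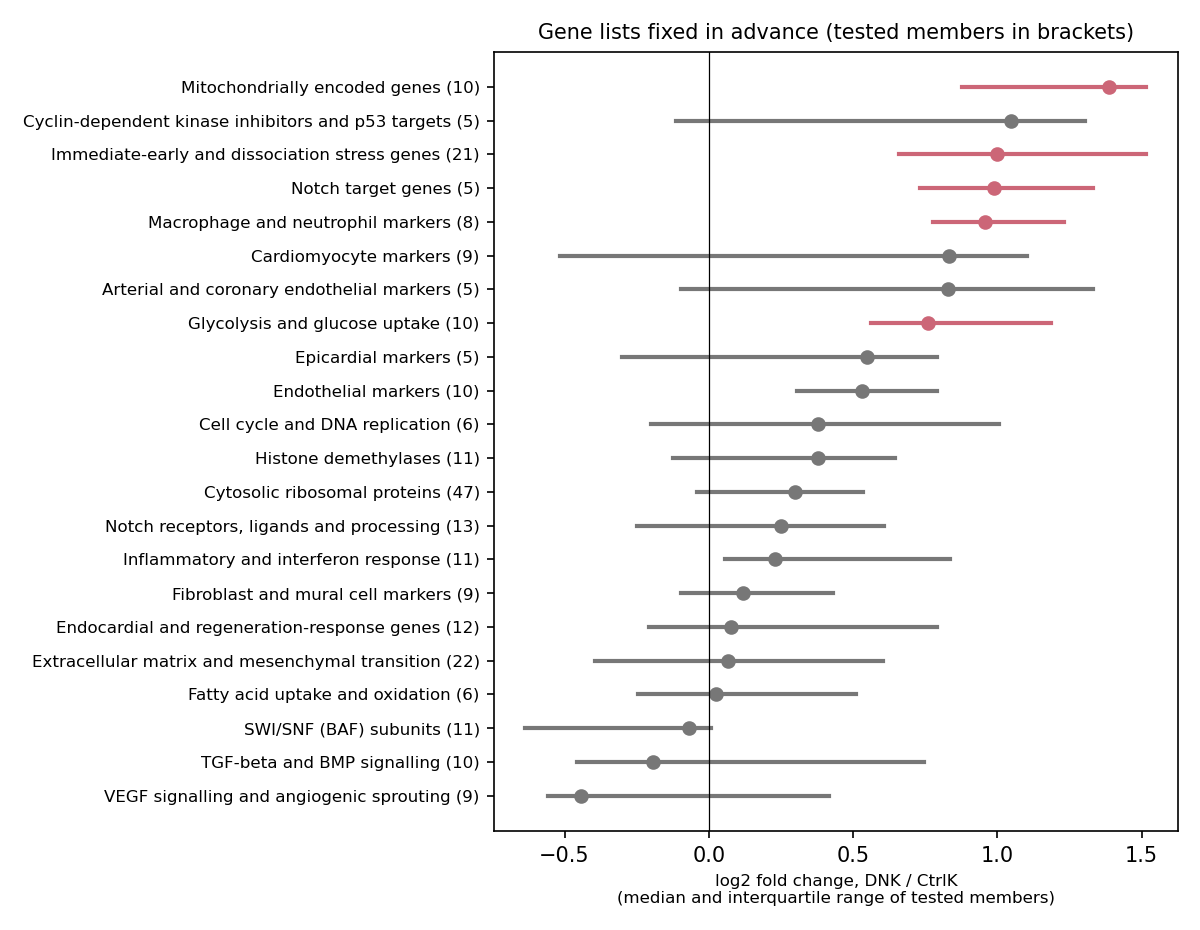
Median (point) and interquartile range (bar) of the log2 fold change of DNK over CtrlK for the tested members of the 22 gene lists with at least 5 tested members, whose number is in brackets. The 5 lists past a camera adjusted p of 0.05 are in red and lie right of 0, and none passed with an estimated correlation.

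The remaining lists did not pass camera as first tested, and several held 1 gene that rose. With no filter the cyclin-dependent kinase inhibitor (adjusted p = 0.00143), arterial (0.00537), histone demethylase (0.0271), ribosomal (0.0337) and inflammatory lists (0.0405) passed, as did the ribosomal list without CtrlK replicate 3 (0.0293) and the inflammatory list without DNK replicate 2 (0.0466). With an estimated correlation their adjusted p was 0.446 for the first and 0.559 for the other 4. By fry the cyclin-dependent kinase inhibitor (adjusted p = 0.0353) and endocardial lists (0.0418) passed, but with an estimated correlation they did not (adjusted p = 0.446 and 0.559). CDKN1B, a cyclin-dependent kinase inhibitor, rose by 1.67 ± 0.36 (adjusted p = 0.0158) among 5 tested genes of its list (2 adjusted over the list alone, camera adjusted p = 0.180). Among 12 endocardial and regeneration-response genes, FOSL1, an AP-1 member, rose by 1.65 ± 0.38 (adjusted p = 0.0193, 2 adjusted over the list alone, camera adjusted p = 0.489). Among 22 extracellular matrix genes, the collagen gene COL1A2 rose by 1.54 ± 0.37 (adjusted p = 0.0229, 1 adjusted over the list alone, camera adjusted p = 0.782). Among 11 inflammatory and interferon genes, SOCS3 (ENSDARG00000026611), an inhibitor of cytokine signalling, rose by 1.25 ± 0.29 (adjusted p = 0.0202, 1 adjusted over the list alone, camera adjusted p = 0.180), while its other copy (ENSDARG00000025428) was at 0.19 ± 0.50 (adjusted p = 0.836). Among 10 TGF-beta and BMP genes, SMAD3 rose by 1.28 ± 0.36 (adjusted p = 0.0453, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.824), while the list had a median of −0.19 and a mean of 0.08. AXIN2, a Wnt target, rose by 1.98 ± 0.54 (adjusted p = 0.0413) among 3 tested Wnt genes. By edgeR kdm7aa was the 1 of 11 histone demethylases that rose (2 adjusted over the list alone, camera adjusted p = 0.318). DESeq2 called 2 genes each in the endocardial, TGF-beta and histone demethylase lists, and limma-voom 0 in the Wnt and histone demethylase lists. In 6 further lists of at least 5 tested members edgeR called 0 genes. These were SWI/SNF subunits (11 tested, 2 at an unadjusted p under 0.05, camera adjusted p = 0.344), cell cycle genes (6 tested, 2 at unadjusted p, camera adjusted p = 0.344), VEGF and sprouting genes (9 tested, 0 at unadjusted p, camera adjusted p = 0.851), fatty acid genes (6 tested, 2 at unadjusted p, camera adjusted p = 0.911), arterial and coronary markers (5 tested, 2 at unadjusted p, camera adjusted p = 0.216) and epicardial markers (5 tested, 3 at unadjusted p, camera adjusted p = 0.546). Cytosolic ribosomal protein genes likewise had 0 calls among 47 tested, with 6 at unadjusted p and a camera adjusted p of 0.136. Adjusted over the list alone, 2 cell cycle and 2 arterial genes passed and 0 in the other 5 of these lists. DESeq2 called 1 cell cycle and 2 ribosomal genes and limma-voom 1 ribosomal gene, and neither called a gene in the other 5. Lymphatic and venous and thrombocyte markers had 4 tested members each with 0 calls by edgeR, DESeq2 or limma-voom, 2 and 1 of them at an unadjusted p under 0.05, and 1 and 0 adjusted over the list alone. No erythroid marker had enough counts to be tested. Among these genes the CDKN1B call held without each library. The others were lost, with the adjusted p in brackets, as follows. FOSL1 was lost without CtrlK replicates 1 (0.0534) and 2 (0.0690) and DNK replicate 1 (0.0775), and COL1A2 without CtrlK replicates 1 (0.0684) and 2 (0.0782) and DNK replicates 1 (0.0838) and 2 (0.0603). SOCS3 was lost without DNK replicates 1 (0.0839) and 2 (0.0591). SMAD3 was lost without each library but CtrlK replicate 3 (0.0750 to 0.160), and AXIN2 without CtrlK replicates 2 (0.114) and 3 (0.0992) and DNK replicates 1 (0.255, log2 fold change 1.224) and 3 (0.0520). Scaled to the 200 most abundant genes none of CDKN1B, FOSL1, COL1A2, SOCS3, SMAD3 and AXIN2 passed, with adjusted p of 0.0689 (SOCS3) to 0.137 (SMAD3), while their log2 fold changes stayed positive. SMAD3 (0.0868) and AXIN2 (0.0715) were also lost with library size alone, and AXIN2 with limma-voom (0.0857).

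By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 270 of 3792 genes differed, 179 higher and 91 lower in DNK. The groups did not overlap for 1169 genes, 30.8% of those tested, where chance gives 10%. Of the 100 most abundant genes 40 were higher and 1 lower, with a median log2 fold change of 0.72, while the 3792 genes had a median of −0.07. The split depended on the scaling. With library size alone 112 genes were higher and 248 lower, scaled to the 200 most abundant genes 67 and 488, and scaled to reads outside genes 501 and 39. The medians over all genes were then −0.39, −0.66 and 0.34. NOTCH1 (ENSDARG00000052094), NRARP and kdm7aa passed under all 4 scalings, and notch2 was lost with library size alone (adjusted p = 0.0763) and when scaled to abundant genes (adjusted p = 0.109). The reads counted outside genes came to 5.49 ± 0.585 per gene count in CtrlK and 3.50 ± 0.286 in DNK (SD, n = 3 each, no overlap), and the 10 most abundant genes held 6.87% ± 1.64 and 13.1% ± 1.02 of gene counts. The number of changed genes was 160, 104, 89, 136 and 159 without CtrlK replicates 1 and 2 and DNK replicates 1, 2 and 3 in turn, and 277 without CtrlK replicate 3.

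**Figure D3:**
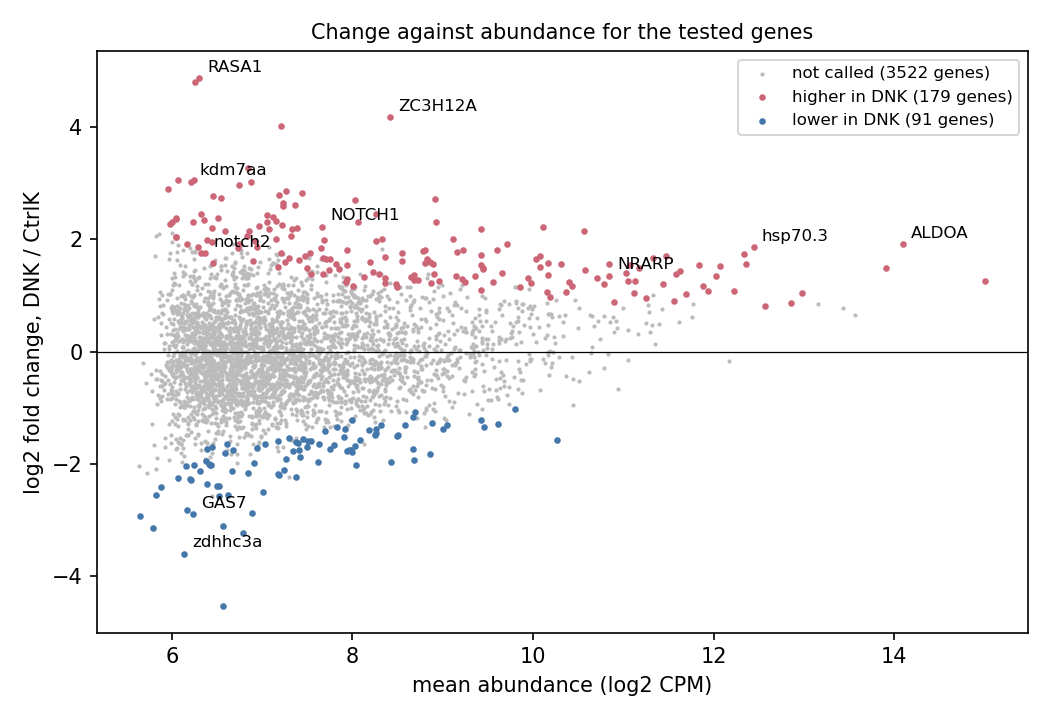
Log2 fold change of DNK over CtrlK against mean abundance (log2 CPM) for the 3792 tested genes, with the 179 genes higher in DNK in red, the 91 lower in blue and the rest in grey. Among the 100 most abundant genes 40 are higher and 1 is lower.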

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

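Reads overlapping more than 1 gene, which the comparison did not use, made up 0.0597% ± 0.00472 of all reads in DNK and 0.0374% ± 0.00785 in CtrlK (SD, n = 3 each). They are given here because each DNK library lay above each CtrlK library in data outside the gene counts. The share of all reads assigned to genes was also higher in each DNK library (1.15% ± 0.108 in CtrlK and 1.48% ± 0.00638 in DNK). The rise of the reads overlapping more than 1 gene may therefore not be separate from it.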

How the results depend on the processing

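The scalings to abundant genes and to reads outside genes, and the background covariate, were chosen after the data were seen. The number of changed genes stayed within 1.5 times of 270 under the planned settings that keep all libraries, from 184 (limma-voom) to 370 (no filter). It was 555 when scaled to the 200 most abundant genes and 540 when scaled to reads outside genes. Genes higher in DNK numbered 112 with library size only, 283 with no filter, 106 with the stricter filter, 67 scaled to abundant genes and 501 scaled to reads outside genes. Genes lower in DNK numbered 248 with library size only, 46 with limma-voom, 488 scaled to abundant genes and 39 scaled to reads outside genes. The scalings differ by construction in the level set to 0, and the stricter filter tested 721 genes. Leaving out 1 library gave 89 to 277 changed genes, 74 to 213 higher and 14 to 64 lower, with fewer samples in each fit. With the background ratio as a covariate edgeR called 0 genes, 0 higher and 0 lower, with 219 at an unadjusted p under 0.05. The covariate separates the groups, so little of the group difference is left to test. Of the 39 named calls, 6 were lost with library size only, 14 scaled to abundant genes, 2 scaled to reads outside genes, 4 with no filter, 2 with DESeq2 and 14 with limma-voom. Of the 270 genes, those that a setting also tested kept their sign under these settings, and 44 changed sign under the covariate.

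The Notch receptor list passed with no filter (adjusted p = 0.0190). Without 1 library it ranged from 0.121 to 0.614. With no filter, which tested 23176 genes, 7 other lists passed that had not as first tested. These were endothelial (0.00576), cardiomyocyte (0.000982), cyclin-dependent kinase inhibitor (0.00143), arterial (0.00537), histone demethylase (0.0271), ribosomal (0.0337) and inflammatory genes (0.0405). With an estimated correlation none of the 7 passed, either with no filter (adjusted p = 0.152 to 0.521) or as first tested (0.446 for the first 3 and 0.559 for the other 4). The endothelial list also passed without CtrlK replicate 2 (0.0328) or DNK replicate 1 (0.0374), the ribosomal list without CtrlK replicate 3 (0.0293) and the inflammatory list without DNK replicate 2 (0.0466). The Notch target list did not pass with an estimated correlation (adjusted p = 0.446) or scaled to reads outside genes (0.0576), and ranged from 0.0154 to 0.165 without 1 library. The cause was not tested. Lists that changed direction did so without passing in either setting. These were cell cycle genes with no filter (adjusted p = 0.826) and without 1 library (0.522 to 0.963), VEGF and sprouting genes with no filter (0.0571) and without 1 library (0.809 to 0.974), extracellular matrix genes scaled to abundant genes (0.979), and fatty acid genes without 1 library (0.681 to 0.99977). Genes that changed sign under an alternative other than the covariate were not called in either. The second copy, NOTCH1 ENSDARG00000103554, was at −0.00761 scaled to abundant genes. dll4 was at 0.18 scaled to reads outside genes and at −0.40 to 0.18 without 1 library. NOTCH3 was at 0.028 with no filter, 0.17 with limma-voom, 0.31 scaled to reads outside genes and −0.48 to 0.29 without 1 library. SMARCA4 was at −0.29 with library size only, −0.026 with limma-voom, −0.53 scaled to abundant genes and −0.28 to 0.26 without 1 library. With the covariate the log2 fold changes that changed sign were 1.37 (dll4), 0.11 (NOTCH3), −1.14 (SMARCA4), 1.31 (TMEM178B), −0.34 (CCND1), −0.16 (RPL6), −0.42 (krt4), −0.25 (hsp70l), −0.21 (hsp70.1), −0.018 (JUND), −0.028 (MT-CO1), −0.21 (MT-CYB), −0.78 (SMAD3) and 1.09 (THBS1), and the cause of the other changes of sign was not tested.

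With the replicate number as a block, 253 genes were called, 169 higher and 84 lower, of which 226 were also called without it. The counts gave no sign that the numbers pair the samples, though so few libraries cannot exclude it. The deviations of same-numbered libraries from their group means correlated at −0.105, −0.0030 and −0.042 across genes, and no library correlated best with its own number. The block ended the named calls of JUND, atp2a2a, notch2 and prlrb, let dlc and CCND1 pass, and changed no other named call. The GC corrections, with and without the block, were not run because no genome was used. With 3 counts worth 13.2 to 17.2 CPM, changes near 2-fold were mostly not detectable at this depth.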

Other observations

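Tests in this part that were chosen after the data were seen are those on libraries scaled to the 200 most abundant genes or to reads outside genes, the variance among the 100 most abundant genes and the correlation with abundance.

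The genes below lie outside the naming rule and were chosen after their values were seen. When libraries were scaled to the 200 most abundant genes, 67 of the 179 higher calls kept their call. They included the chaperone and co-chaperone genes HSPA4 (ENSDARG00000004754, log2 fold change 1.91 ± 0.32 as first tested), STIP1 (1.66 ± 0.25), HSPA2 (1.73 ± 0.30) and HSP90AA1 (1.08 ± 0.26). The lipid droplet coat genes PLIN2 (2.43 ± 0.47) and plin3 (1.81 ± 0.39) were also among them. So were CSF3R (2.70 ± 0.46), il13ra1 (2.31 ± 0.36), BIRC2 (2.15 ± 0.33) and REL (1.69 ± 0.37). PIK3CB, a catalytic subunit of PI3-kinase (2.30 ± 0.49), and fgd5a (2.21 ± 0.27) kept their calls too. EPAS1, the hypoxia-inducible factor HIF-2 alpha, rose by 1.40 ± 0.27. These values are those as first tested, and the rises were smaller when scaled to abundant genes. On that scale HSP90AA1 was at 0.52 (edgeR adjusted p = 0.0478), plin3 at 1.25 (0.0485) and EPAS1 at 0.82 (0.0246). When scaled to reads outside genes, 39 of the 91 lower calls kept their call. Among them were zgc:123295 (−4.53 ± 0.74 as first tested and −4.10 on that scale), LRRK2 (−2.20 ± 0.47 and −1.78), gpx1b (−1.83 ± 0.38 and −1.40) and ahr1a (−2.39 ± 0.55 and −1.98). The odorant receptor name or93a8, given above under the naming rule, also kept its call (−2.74 on that scale). A kept call therefore does not clear a gene of read background. These genes were picked singly and no group of them was tested.

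The real grouping gave 270 changed genes and the highest of the other 9 splits gave 0. With 10 splits of 6 libraries (the real one counted as 1), the splits are too few for a share under 0.05.

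Log2 fold changes correlated weakly with abundance (r = 0.155 across 3792 genes), with 40 higher and 37 lower calls below the median abundance and 139 and 54 above it. A candidate explanation is a larger share of reads that do not come from transcripts in the CtrlK libraries. In 360 genes named as odorant, vomeronasal-type and trace amine receptors, gamma crystallins and opsins, not expected in heart endothelium, summed CPM was 3368 ± 626 in CtrlK and 2099 ± 273 in DNK (SD, n = 3 each, log2 ratio −0.682, −0.635 without called genes), close to the log2 ratio of −0.648 of reads outside genes per gene count, and across genes the slope on that read ratio within groups correlated with the group difference (r = −0.203, and −0.173 and −0.122 in CtrlK and DNK alone, genes not being independent). The log2 fold changes of the 100 most abundant genes had 6.09 times the variance that their SE gives. This goes against dilution by the same factor in all of them. Background can hold a different share of each gene's counts, so the variance does not decide whether dilution is the whole cause. A change of RNA content per cell with the dominant-negative Brg1 was not tested and stays open, as it would also move the share of such reads.

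Of 6 tested heat shock genes of the fixed stress list, 3 close hsp70 copies rose in DNK, HSPB1 (adjusted p = 0.708), HSPA5 (0.0902) and dnajb1b (0.109) did not pass, and the 6 were not tested as a set. Chaperone genes outside these 6 also rose, among them HSPA4 (ENSDARG00000004754), HSPA2 and HSP90AA1, which were picked after their values were seen. When scaled to the 200 most abundant genes, the median of the 6 listed genes stayed at 0.965 and the 3 hsp70 copies kept their call. Dilution would bring them near 0 there only if background held a like share of their counts and the scaling genes' counts. Those shares were not measured, so the scaling does not decide whether dilution accounts for these 3. A dissociation stress response in the DNK cells is a candidate explanation. Scaled to the 200 most abundant genes, the 15 tested immediate-early genes had a median of 0.364 (quartiles 0.0611 and 0.480), and 12 were positive. EGR3 (−1.25), KLF6 (−0.80) and FOS (−0.65) were negative. By edgeR 0 of the 15 passed on that scale (4 at an unadjusted p under 0.05) and 2 did as first tested. An effect of dominant-negative Brg1 on these genes was not tested and stays open.

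All 8 tested macrophage and neutrophil markers had positive log2 fold changes, but by edgeR 0 passed over all genes (4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), and their list passed camera (adjusted p = 0.00365) but not with an estimated correlation (adjusted p = 0.446). If they are higher, more such cells among the sorted cells may account for it. The sort on kdrl:eGFP selects for endothelial cells, but how far it removed such cells was not tested. When scaled to the 200 most abundant genes, 7 of 8 members stayed positive. This count of signs cannot tell more such cells from higher expression within cells. The most abundant members tested, cd74b and cd74a, were at 402 ± 265 and 286 ± 33.4 CPM in CtrlK and at 713 ± 292 and 561 ± 92.1 CPM in DNK (SD, n = 3 each), and none of the 8 is in another of the lists. Dilution cannot be told apart from more such cells. The median on that scale, 0.420, lies between the limits set for and against dilution after the data were seen. The members' SE are 0.318 to 0.532. A change of expression within endothelial cells was not tested.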
